A study of Mus musculus with 2 samples.

How the data were processed

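Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in the mouse erythroid cell line G1E-ER4. Per the labels, both libraries came from 50000 cells each, exposed for 24 hours to 17beta-estradiol at 10 nM, and are biological replicates 1 and 2 of the same group. There was no untreated group, so the comparisons were made between the replicates, between classes of genomic region and between gene lists. The labels call the libraries biological replicates and say no more about the cultures, so the spread between them is the only measure of replicate error here.

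The files analysed were peak lists in the narrowPeak layout, on the mm10 assembly per the labels. The aligner, the peak caller, the read filters, any shift of read ends for the transposase and all software versions are not given in the sources used here. Read counts per library are likewise unknown, so depth was described only through the number of regions called. Per the file list deposited with the samples, the authors made peak lists from each library, from pseudoreplicates, from the pooled libraries and from a comparison of the replicates by irreproducible discovery rate (IDR). The same deposited list names an exclusion list of regions among the inputs of the thresholded lists. The signal of a peak is the authors' per-peak enrichment value, whose scaling is not given in the sources used here, and it was used only to rank or describe peaks within a list. The score in the deposited ranked lists is −log10 of the global IDR. Each peak of the deposited thresholded lists was found in its ranked list with a global IDR below 0.05, which was checked peak by peak. The ranked lists held more such peaks on the chromosomes than the thresholded lists did (29468 against 29337 for true replicates, 30303 against 30171 for pooled pseudoreplicates, 19625 against 19510 for library 1 and 21678 against 21571 for library 2), and the cause was not tested. The ranked list of true replicates holds, in the authors' layout, the −log10 p of each peak in each replicate, and these values were used for the correlation between replicates. The analysis plan named log2 signal for that correlation, and −log10 p was used in its place because the deposited replicate columns held it. In all, 13 peak lists were read.

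The conservative list, made by the authors from the true replicates, was the main list. Overlapping peaks of several summits were merged, so that a region counted once, and the summit of largest signal stood for the region. Regions were annotated with GENCODE release M21 on GRCm38, whose chromosome lengths exceed the largest peak end on each chromosome. A promoter region had its summit within 1 kb of any of 54355 annotated transcription start sites (TSS) of protein-coding transcripts, and every other region was called distal. The other regions were divided into exon, intron and intergenic. The share of the genome in each class was computed in the same way for every base. Scaffolds outside the chromosomes were not in the thresholded lists and were left out.

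Regions of the replicates were called shared where the overlap was at least 50% of the shorter region, and 100 circular shifts of the list along its chromosomes gave the overlap expected by chance. Confidence intervals of shares are 95% Wilson intervals, and they cover counting error only. The correlation between replicates runs across peaks, which are not independent replicates, so no p-value is given for it.

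For gene lists, 15 lists with 246 protein-coding genes were written from general knowledge of blood cell biology: globin genes, heme synthesis, red cell membrane and skeleton, erythroid transcription factors and cofactors, erythroid receptors with iron uptake and survival, progenitor genes, megakaryocyte, myeloid and mast cell, lymphoid, pluripotency, liver, neuron, muscle, housekeeping and estrogen receptor targets. A gene had a promoter region where any region overlapped the 1 kb around any of its TSS. That rule differs from the summit rule above, so the same region can stand at a promoter and still have a distal summit. The share of genes with a promoter region was compared with that of all other protein-coding genes by a two-sided Fisher's exact test. The mean number of distal regions within 50 kb of the gene body was compared with 10000 random gene lists of the same size by a two-sided permutation test. Both families of 15 tests were adjusted by the Benjamini-Hochberg method over the lists. Genes are not replicates, so these tests describe the peak lists of these libraries, and each replicate's own list was tested as well.

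For motifs, 17 sequence patterns were searched on both strands in the 201 bp around each summit and in 2 flanking windows of the same width centred 1 kb away, outside every peak of the lists read. Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the motifs, was used separately in distal and promoter regions. The GATA pattern was WGATAR, and the E-box GATA composite was a CTG and a WGATAA 7 or 8 bp apart. A pair of scrambled GATA patterns with the same bases served as controls. Matches were exact to the pattern, so a motif share counts sequence and not protein binding.

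Regions per megabase were computed for each chromosome. The signal of promoter regions was also compared between chromosomes within 20 bins of −log10 p, with a 95% bootstrap interval for X. Regions called in 1 replicate only were compared with shared regions of the same library by two-sided Fisher's exact tests. Regions are not replicates, so the p-values of these tests and of the motif tests cover counting error only. The text names, per gene list, up to 4 genes with the region of largest signal at the promoter or nearby and up to 2 genes with none. It also names 18 loci of blood cell genes with their regions within 100 kb, the genes nearest the 10 regions of largest signal, the 10 genes with the most regions within 50 kb and the 10 windows of 100 kb with the most regions. Some genes and 1 window chosen by these rules are not reported here. Other genes named as members of a small count were chosen after their values were seen.

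The grouping, the tests, the gene lists, the motifs, the rule for naming genes and a set of other settings were fixed before the data were examined. Those settings were other peak lists, regions below the median signal for the comparison of regions called in 1 replicate only, other overlap rules, promoter widths of 500 bp and 2 kb, gene distances of 20 and 100 kb, motif windows of 50 and 200 bp each side, a shuffled background that keeps dinucleotides, random lists matched on the CpG ratio of the promoter in 10 bins or on gene length in 5 bins and TSS number, and leaving out each replicate. The CpG ratio was taken within 1 kb of the most upstream TSS of each gene, while its promoter region could stand at any TSS. Alternatives added after the data were seen were the signal value for the correlation, 1 gene per locus, an older replicated list marked as archived in the deposited file list, and leaving out the 100 regions of largest signal. Because the lists hold no group contrast, no test between groups and no regrouping of samples was possible.

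The overlap of regions, the gene list tests, the motif scan and the shuffle were tested on simulated data, and the other steps were not. Planted overlap of 69.8% of 14012 regions was recovered at 100%, with false overlap of 0.0236%. Over 21829 genes, the Fisher test found 88% of planted lists and called 1% of random ones, and the permutation test found 95% and called 0%. The simulated genes were independent and their state random, so these rates do not cover lists whose genes share regions or differ in CpG ratio. For the motif scan, a GATA site was planted in a random part of 20080 windows of genomic sequence. The scan then matched 44.1% of the windows, which are the planted ones and those it already matched before planting. Because matches are exact to the pattern, that share was fixed in advance and tests little. The odds ratio was 1.78 with planted sites and 1.01 where nothing was planted. The programs were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, pysam 0.24.0, samtools 1.23.1 and BLAST 2.17.0, with random seed 1.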

Results

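Accessible chromatin was mapped in G1E-ER4 cells, a mouse erythroid progenitor line derived from cells that lack Gata1 and carrying a GATA1 protein fused to the ligand-binding domain of the estrogen receptor. Estradiol activates the fusion protein, and the cells then mature along the red cell path. The libraries, replicates 1 and 2, were made from 50000 cells each after 24 hours in 10 nM 17beta-estradiol. No untreated cells were analysed here, so no value given is a change caused by estradiol. Read depth was unknown, and the lists that passed the irreproducible discovery rate (IDR) threshold held 14012 regions in replicate 1 and 15564 in replicate 2. The conservative list, of regions reproducible between the replicates, held 20080 regions that covered 10.8 Mb, or 0.396% of the genome, with a median width of 496 bp. All coordinates are on mm10, and the signal is the authors' value per peak.

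The first question was whether the replicates marked the same regions. Of the regions of replicate 1, 12351 (88.1%, 95% Wilson interval 87.6 to 88.7) were shared with replicate 2, and of those of replicate 2, 12361 (79.4%, 78.8 to 80.05) were shared with replicate 1. Shifted lists overlapped at 0.394% and 0.355% on average, and at most at 0.521% and 0.482%. The regions shared included the promoters of Slc25a37, the mitochondrial iron importer, and of Epb42, a protein of the red cell membrane. The larger list exceeded the smaller by a ratio of 1.11, and the list made from pooled pseudoreplicates exceeded the conservative list by a ratio of 1.03. Of the conservative regions, 60.7% were called in both replicates' own lists, 6.16% in replicate 1 alone, 11.7% in replicate 2 alone and 21.4% in neither. Across 59642 peaks, which are not independent, the −log10 p of the replicates had a Spearman's rho of 0.786 and a Pearson's r of 0.834 on the log2 scale. The rho was 0.810 over promoter peaks and 0.726 over distal peaks.

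Promoters took up the largest share of the regions of the conservative list. Summits of 9497 regions (47.3%, 46.6 to 48.0) lay within 1 kb of a protein-coding start site, a window that makes up 2.37% of the genome, which is a 19.97-fold excess. Introns held 5819 regions (29.0%), intergenic sequence 3907 (19.5%) and exons 857 (4.27%). In the replicates' own lists the promoter share was 57.2% ± 2.30 (SD, n = 2), above that of the conservative list by more than the replicate spread. Promoter summits stood at a median of −39 bp from the start site, which is upstream, and 79.5% of them were within 200 bp. Distal summits lay a median of 15.5 kb from the nearest start site, and 81.6% were within 50 kb. The share of promoters went with peak strength, from 39.0% in the lowest 10% of regions by signal through a minimum of 27.9% to 82.1% in the highest 10%. Among the looser replicated peaks the promoter share was 27.4%, and in the archived replicated list it was 14.01%.

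Genes of the red cell program had promoter regions more often than other genes. A promoter region was present at 18 of 21 genes of the red cell membrane and skeleton, 17 of 20 erythroid transcription factors and cofactors, 15 of 16 genes for erythroid receptors, iron uptake and survival, and 12 of 15 heme synthesis genes, against 42.3% of all 21829 protein-coding genes. Genes of other tissues had them less often: 0 of 15 liver genes, 1 of 15 muscle genes, 1 of 15 pluripotency genes, 2 of 15 neuron genes, 2 of 20 myeloid and mast cell genes and 3 of 20 lymphoid genes. The adjusted p-values of Fisher's exact test were 0.000315 for the membrane list, 0.000472 for the transcription factors, 0.000178 for the receptor list and 0.00783 for heme synthesis. They were 0.000942 for liver, 0.0109 for muscle and for pluripotency, 0.045 for neuron, 0.00659 for myeloid and mast cell genes and 0.0189 for lymphoid genes. All 18 housekeeping genes had a promoter region (adjusted p = 2.78e-06, Fisher's exact test). The shares of the globin genes (5 of 9), progenitor genes (7 of 17), megakaryocyte genes (4 of 17) and estrogen receptor targets (4 of 13) did not pass the test against other genes, with adjusted p-values of 0.585, 1, 0.179 and 0.618 by Fisher's exact test. Every list past the threshold was also past it in each replicate alone. Over the replicates, the share was 73.8% ± 3.37 for the membrane list, 72.5% ± 3.54 for the transcription factors, 93.8% ± 0 for the receptor list, 76.7% ± 4.71 for heme synthesis, 5% ± 0 for myeloid and mast cell genes and 0% ± 0 for liver (SD, n = 2).

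Among the membrane genes with the strongest regions, Epb41, the protein 4.1 of the membrane skeleton, had a promoter region on chromosome 4 at 132049012 to 132049418 with a signal of 17.7, and Epb42 had a promoter region on chromosome 2 at 121036551 to 121037358 with a signal of 16.4. Slc4a1, the band 3 anion exchanger, had a weaker promoter region (signal 7.54), and Sptb, the erythroid beta spectrin, had a promoter region with a signal of 9.61. Aqp1, a water channel, had no region in the conservative list, to which all gene calls here refer unless another list is named. In heme synthesis, Slc25a37 had a promoter region with a signal of 17.0 on chromosome 14 at 69284902 to 69285394, Flvcr1, a heme exporter, had a signal of 14.5 and Abcb10, a mitochondrial transporter, had 6.13. Alas2, the erythroid enzyme of the first step of heme synthesis, had no region at its start site but had 3 distal regions. Alas1, the enzyme of the same step in other cells, had no region in that list, but replicate 2 had a distal region near it and the looser replicated list a promoter region. Of the transcription factors, Nfe2 (signal 11.98), Lmo2 (11.5), Ikzf1 (11.4) and Klf13 (7.68) had promoter regions, while Gfi1b, Sox6 and E2f2 had none. In the receptor list, the promoters of Hmox1, which degrades heme, Slc11a2, an iron transporter, Steap3, a ferric reductase, and Trim10 had signals of 16.9, 16.1, 13.8 and 13.7. Trim58 was the only member of that list without a promoter region.

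In the lists that were not enriched, Hba-a1 and Hba-a2, the adult alpha-globin genes, had promoter regions, and Hba-x and Hbq1a, further members of the cluster, had none. Of the progenitor genes, Runx1, Meis1 and Kit had promoter regions with signals of 7.99, 11.6 and 9.67, Fli1 had only distal regions, and Erg and Hoxa10 had no region. The 4 megakaryocyte genes with a promoter region were Pf4, Itga2b, Gp1ba and Tubb1, while the strongest nearby regions belonged to Gp6, Gp9, Treml1 and Itgb3, and Gp1bb and Gp5 had none. Spi1, which encodes PU.1, and Fcgr3 were the 2 myeloid genes with a promoter region, and that of Fcgr3 was in neither replicate's own list. Ltf, Cebpe, Csf1r and Prg2 had distal regions only, and Cebpa and Epx had none. The 3 lymphoid genes were Gata3, Ebf1 and Rag1, with signals of 19.9, 18.2 and 7.89. Cd79a had distal regions only, and Bcl11b had none. In the remaining lists, promoter regions stood at Dppa4, Slc17a7, Tubb3, Ryr1, Xbp1, Rara, Nrip1 and Ctsd. Of the promoter regions named so far, that of Slc17a7 was in neither replicate's own list, those of Slc4a1, Abcb10 and Ryr1 were called in replicate 1 only, and those of Pf4, Rag1 and Tubb3 in replicate 2 only. The genes Tdgf1, Tfcp2l1, Nanog, G6pc, Apoa1, Apoa2, Neurog2, Syt1, Ckm, Myh6, Myh7 and Acta1 had distal regions nearby and no promoter region. The conservative list had no region for Dppa5a, Esrrb, Afp, Alb, Camk2a, Dcx, Actn2, Mb, Ccnd1 or Cxcl12, while replicate 1 had a distal region near Afp and Alb and replicate 2 near Camk2a. Of the genes above without a region, Erg had a distal region in replicate 1, and Gp1bb and Cebpa in replicate 2. The housekeeping promoters of Rab7, Rplp0, Actb and Pgk1 had signals of 19.3, 22.0, 9.75 and 20.998.

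The promoter calls depended on the list, on peak strength and on promoter sequence. In the looser replicated list 4 lists in place of 6 were below other genes, since myeloid and mast cell genes (30%, adjusted p = 0.243) and neuron genes (20%, adjusted p = 0.0602) did not pass Fisher's exact test. When only regions above the median signal were kept, 1 list was above other genes in place of 5, and it was the housekeeping list. Against random genes matched on the CpG ratio of the promoter, the lists below fell from 6 to 2, which were pluripotency (adjusted permutation p = 0.0065) and neuron (0.021), while the globin genes moved above the 11.2% of matched genes (55.6%, adjusted permutation p = 0.0018). The 9 globin genes form 2 loci and the random genes were drawn singly, so that p-value treats neighbours as independent. Among the open globin genes, Hbq1b was open in neither replicate's own list and Hbb-bt in replicate 2 only.

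**Figure D1:**
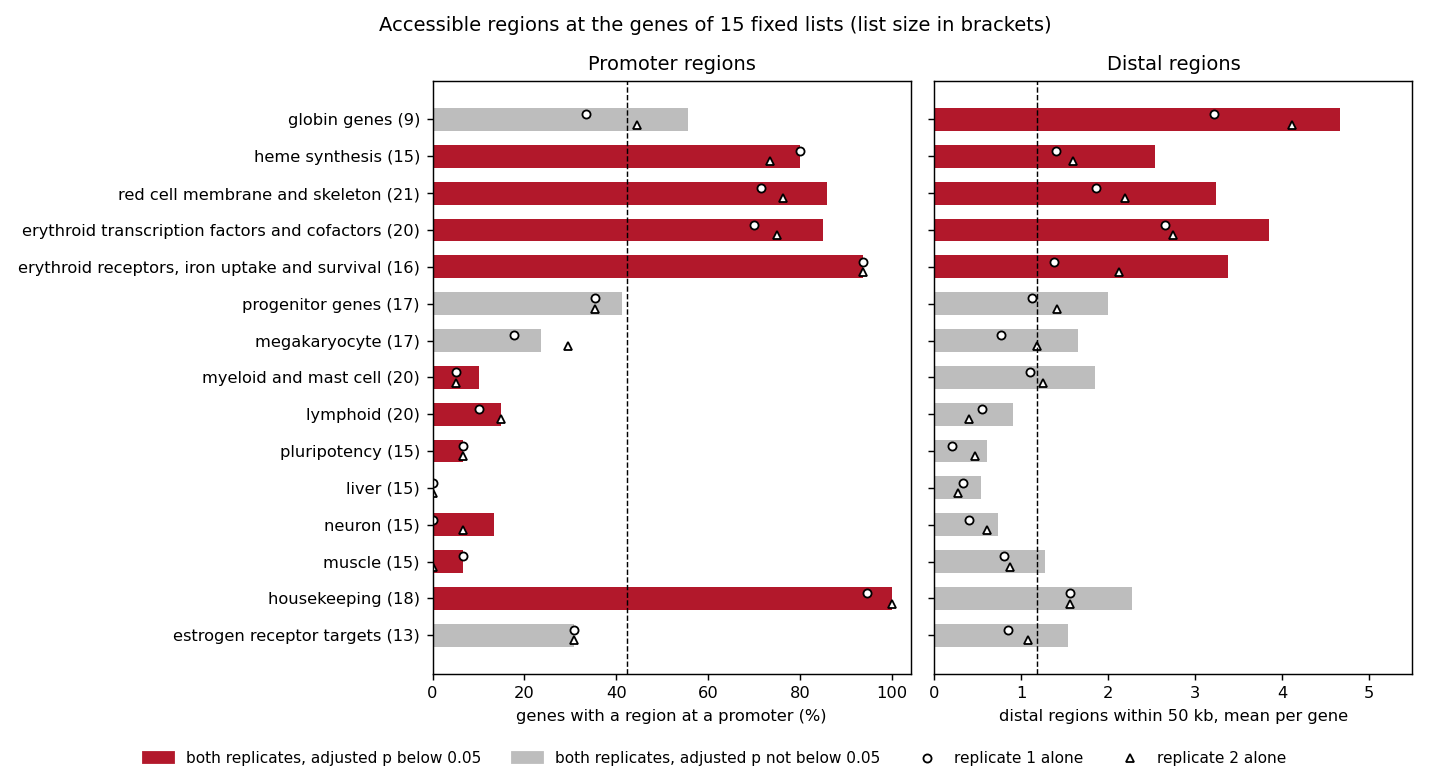
Percent of genes with a region at a promoter (left) and mean number of distal regions within 50 kb per gene (right) for the 15 gene lists, with list size in brackets. Bars give the conservative list, red where the adjusted p is below 0.05 and grey where it is not, circles and triangles give replicates 1 and 2 alone, and dashed lines give the value over all protein-coding genes (42.3% and 1.18 regions); all 5 lists of the red cell program are red on the right.

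Distal regions were also more numerous around red cell genes. Within 50 kb of the gene body there were on average 4.67 distal regions for the globin genes, 3.85 for erythroid transcription factors and cofactors, 3.38 for the receptor list, 3.24 for the membrane list and 2.53 for heme synthesis genes, against 1.18 over all genes. The adjusted permutation p was 0.00975 for each of the first 4 lists and 0.0342 for heme synthesis. Zfpm1, the GATA1 cofactor FOG1, and Klf13 had the most within the transcription factor list, with 10 each in the conservative list. In each replicate alone they had 7 and 6, and Ikzf1 had 8 in replicate 1. Over the replicates, the mean was 3.67 ± 0.629 for the globin genes, 2.70 ± 0.0707 for the transcription factors, 1.75 ± 0.530 for the receptor list, 2.02 ± 0.236 for the membrane list and 1.5 ± 0.141 for heme synthesis (SD, n = 2). The mean for housekeeping genes was 2.28, with an adjusted permutation p of 0.0545. That list passed in replicate 1 (adjusted permutation p = 0.0307) and not in replicate 2 (0.0870). Against random lists matched on gene length and number of nearby start sites, whose mean was 1.11, it passed (adjusted permutation p = 0.02), so the distal excess was not limited to red cell lists there, with 6 lists above in place of 5. The other lists did not pass the permutation test: progenitor genes averaged 2.00 distal regions (adjusted p = 0.177), myeloid and mast cell genes 1.85 (0.208), megakaryocyte genes 1.65 (0.393), estrogen receptor targets 1.54 (0.536), muscle 1.27 (0.823), lymphoid 0.900 (0.558), neuron 0.733 (0.414), pluripotency 0.6 (0.254) and liver 0.533 (0.209). In the single replicates, heme synthesis did not pass (adjusted permutation p = 0.0855 in replicate 1 and 0.0870 in replicate 2) and the receptor list did not pass in replicate 1 (adjusted permutation p = 0.0855). Heme synthesis also failed to pass in the pooled pseudoreplicate list (adjusted permutation p = 0.0810) and in the replicated list (0.0682). The same held above the median signal (0.115), within 20 kb (0.0685) and within 100 kb (0.127). That list passed against random lists matched on gene length and number of nearby start sites (adjusted permutation p = 0.03), and with 1 gene per locus. The globin genes form 2 loci, and with 1 gene per locus the adjusted permutation p of that list was 0.0615.

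At the alpha-globin locus on chromosome 11, 13 regions lay within 100 kb of Hba-a1. The strongest after the promoter of Snrnp25 (signal 16.6) stood at −27.2 kb from the start site of Hba-a1, at 32256007 to 32256692, in a noncoding exon within Nprl3, with a signal of 15.9. It carried the E-box GATA composite at its summit. The introns of Nprl3 are known to hold enhancers of the alpha-globin genes. Other regions within Nprl3 stood at 32245468 to 32246037, with the composite and a signal of 14.01, at 32250844 to 32251295 (signal 13.6) and at 32265109 to 32265475 (signal 8.09, called in replicate 2 only), both with a GATA motif. The promoters of Hba-a1 and Hba-a2 had signals of 11.2 and 14.5, and no region stood at the promoter of the embryonic gene Hba-x. At the beta-globin locus on chromosome 7, 8 regions lay within 100 kb of Hbb-bs. Promoter regions stood at the adult genes Hbb-bs (signal 9.69) and Hbb-bt (6.61) and none at the embryonic genes Hbb-y and Hbb-bh1. Upstream of Hbb-y, where the locus control region lies, 4 regions stood at 103859117 to 103859472, 103860903 to 103861300, 103865692 to 103866082 and 103870727 to 103871049, with signals of 7.35, 12.8, 7.29 and 10.5. The first and the last of them carried the composite, and the third was called in replicate 1 only and the last in replicate 2 only. Farther upstream, near Olfr65, 2 regions with a GATA motif stood at 103910050 to 103910463 and 103913037 to 103913472, with signals of 7.77 and 10.1, the latter called in replicate 2 only. Reads from Hba-a1 and Hba-a2, and from Hbb-bs and Hbb-bt, can be hard to place because the pairs are near copies, so how the signal divides within each pair is uncertain.

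**Figure D2:**
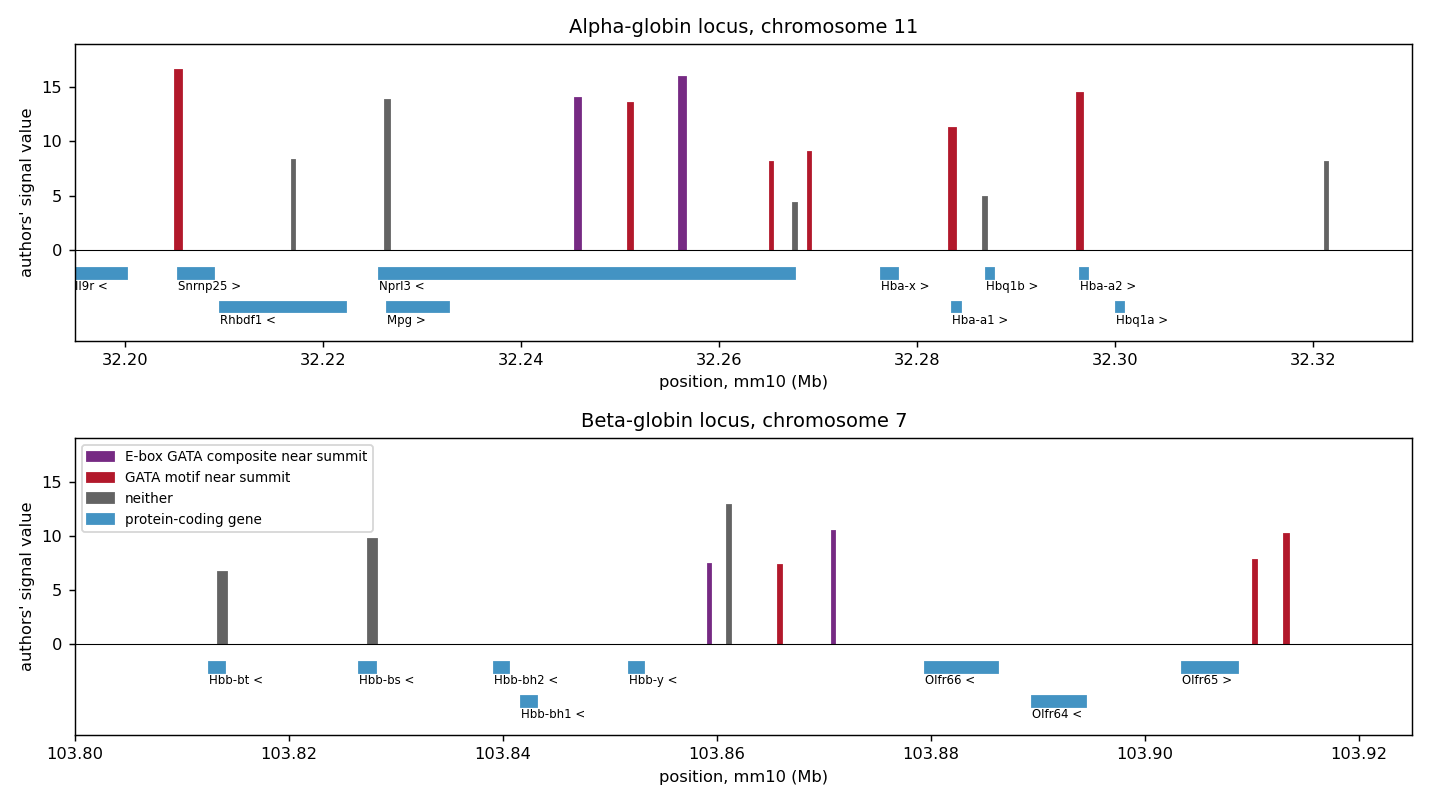
Regions of the conservative list at the alpha-globin (top) and beta-globin (bottom) loci, with position in Mb on mm10 and bar height the authors' signal value; colours mark the motif within 100 bp of the summit, and blue boxes are protein-coding genes with their strand. The alpha-globin panel has its strongest composite-bearing region within Nprl3 (signal 15.9), and the beta-globin panel has 6 regions upstream of Hbb-y.

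The other blood cell loci named in advance had 5 to 20 regions within 100 kb. Gata1 had a promoter region on chromosome X at 7967831 to 7968152 with a signal of 7.02, called in replicate 2 and not in replicate 1, and an intron region at 7971094 to 7971741, at −3.54 kb from the nearest start site, with a GATA motif and a signal of 11.8. Its 9 regions within 100 kb included the promoters of Hdac6 (signal 23.6), Pqbp1, Pim2, Slc35a2 and Suv39h1. Regions in coding exons of Gata1 stood at 7959718 to 7960142 (signal 6.92) and 7961922 to 7962571 (signal 6.27). The cells carry a GATA1 fusion gene, and whether reads in these exons came from it was not tested. Gata2, a progenitor factor, had 1 weak promoter region on chromosome 6 at 88198242 to 88198741 (signal 4.90), which was in neither replicate's own list. Kit, the stem cell factor receptor, had a promoter region (signal 9.67) and intron regions that included 75607909 to 75608543 on chromosome 5, with the composite and a signal of 8.65. Tal1 had 9 regions within 100 kb, and the strongest with a motif stood 39.5 kb downstream of its start site on chromosome 4 at 115095524 to 115096438, with the composite and a signal of 10.98. Its own promoter region (signal 5.34) was in neither replicate's list. Klf1 had 20 regions within 100 kb, in a gene-dense stretch, and its promoter region at 84901162 to 84901444 on chromosome 8 had the composite and a signal of 7.13. That region was in neither replicate's own list, although replicate 2 had another region at the Klf1 promoter. Alas2 had intron regions on chromosome X at 150549502 to 150550108, with the composite and a signal of 12.4, and at 150564611 to 150565342, with a GATA motif and a signal of 15.6. Slc4a1 had an intron region at 102363611 to 102364018 on chromosome 11, with the composite and a signal of 11.003. Zfpm1 had 13 regions within 100 kb, of which 11 were distal and 7 had a GATA motif. Lmo2 had 9 regions, 5 of them with a GATA motif. Gfi1b had 7, and those at 28597751 to 28598543, 28602196 to 28602562 and 28596054 to 28596428 on chromosome 2, all intergenic, carried GATA motifs; the first was called in replicate 1 only and the last in replicate 2 only. Epor, the erythropoietin receptor, had 9 regions and a promoter signal of 12.3. Nfe2 had 15 regions, and its promoter region at 103258113 to 103258815 on chromosome 15 carried the composite. Spi1 had 12 regions. A promoter region on chromosome 2 at 91096510 to 91096893 (signal 8.79) stood at an internal start site, 14.3 kb downstream of the first one. The region at the first start site, 91082933 to 91083421 (signal 8.66), was in neither replicate's own list. An intron region with the composite stood at 91060581 to 91061357, nearest to Psmc3 (signal 12.6). Myc had 5 regions, 4 of them promoter regions with signals of 3.94 to 5.65.

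Distal regions were rich in the motifs of erythroid factors. The GATA motif stood near 50.9% of 10583 distal summits and in 29.7% of flanking windows (odds ratio 2.45, 95% interval 2.33 to 2.57, adjusted p = 2.32e-279 by Fisher's exact test), while the scrambled patterns were less frequent at summits (odds ratios 0.723 and 0.546). The E-box GATA composite, to which complexes of TAL1 and GATA1 bind, had an odds ratio of 14.5 (11.96 to 17.6), with 8.58% of distal summits against 0.643% of flanks. The KLF motif, bound by KLF1 and its relatives, had 3.62 (3.36 to 3.90), and the NF-E2/AP-1 motif had 3.03 (2.73 to 3.37). The other distal odds ratios were 100.2 for CTCF, the insulator protein, 4.99 for ETS, 5.29 for SP1, 4.70 for NRF1, 2.89 for PU.1, 2.67 for NFY, 1.74 for RUNX and 1.45 for STAT, all past the adjusted threshold. Distal NRF1 rests on 8 summits and 3 flanks and had 8.84 in replicate 2 alone, and ETS had 7.73 in replicate 1 alone. The estrogen response element, MEF2 and HNF1 were not (odds ratios 0.881, 0.688 and 0.294, adjusted p = 1, 0.139 and 0.461 by Fisher's exact test). Over the replicates, the GATA share of distal regions was 52.9% ± 0.559 and the composite share 9.66% ± 0.519 (SD, n = 2).

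Promoter regions had a different set of motifs. The odds ratio was 127 for NRF1, which rests on 2 flanking windows with the motif and was 240 in replicate 2 alone, 38.1 for ETS, 21.5 for SP1, 15.7 for NFY, 10.4 for CTCF, 8.80 for KLF, 2.23 for the E-box GATA composite and 1.72 for PU.1. GATA, with 0.373, was close to the scrambled patterns at 0.348 and 0.251. The NF-E2/AP-1 (0.747), RUNX (0.667) and MEF2 (0.341) motifs were less frequent than in flanks, and STAT was not past the threshold (0.866, adjusted p = 0.0755 by Fisher's exact test). The estrogen response element and HNF1 were found near 1 and 2 promoter summits. Against shuffled sequence of the same windows, the GATA odds ratio at promoters turned to 1.299, and those of NF-E2/AP-1, RUNX, STAT and MEF2 turned to 1.48, 1.498, 2.79 and 4.004, so that 14 motifs in place of 8 were above background, the first scrambled pattern (1.13) among them.

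**Figure D3:**
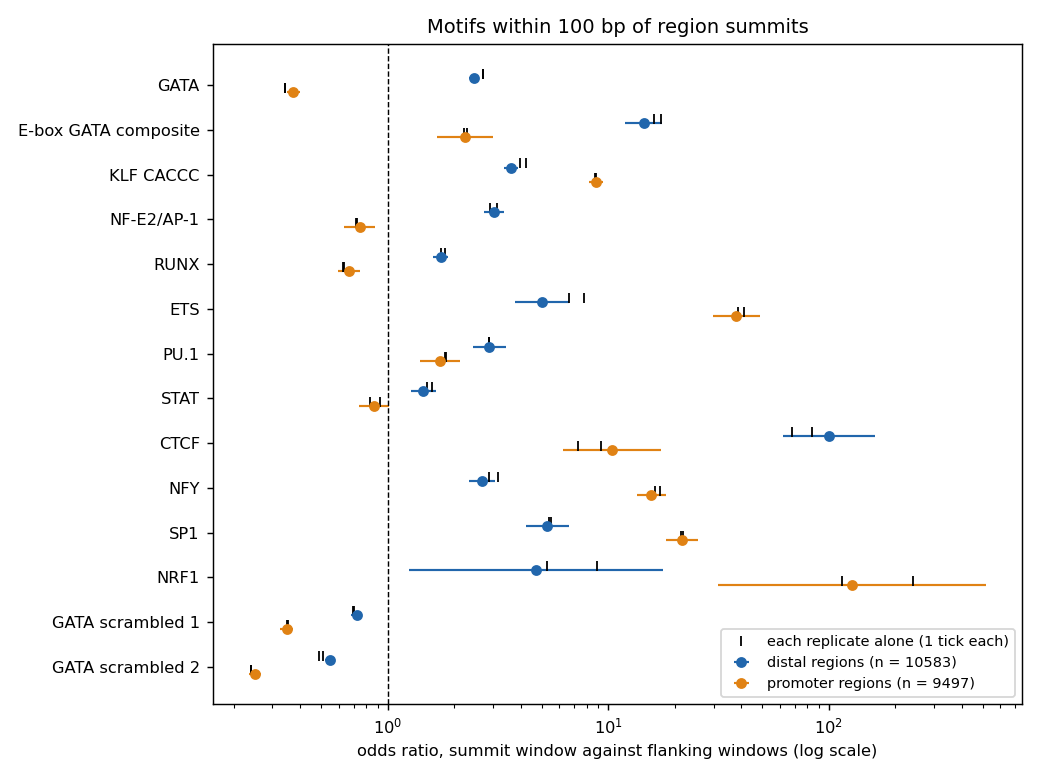
Odds ratios (log axis) of 14 of the 17 motif patterns within 100 bp of the summit against flanking windows, for distal (blue) and promoter (orange) regions, with 95% intervals that cover counting error; black ticks are the values of each replicate alone. The estrogen response element, MEF2 and HNF1, each rare, are not drawn, and the largest distal values are those of CTCF (100.2) and the E-box GATA composite (14.5).

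The 10 regions with the largest signal were not near erythroid genes. The strongest, on chromosome 2 at 69355472 to 69355731, had a signal of 49.5 and lay in intergenic sequence at −13.0 kb from the start site of Abcb11, the bile salt exporter. The next were in an intron near Rtl10 on chromosome 16 at 18533126 to 18533396 (signal 46.6), and in intergenic sequence near Pak3 on chromosome X at 143482937 to 143483177 (signal 46.0). The genes nearest to the others were Epm2a, Igf2bp3, Nxph1, Gm31371, 4930467E23Rik, Peak1 and Gm15319, with signals of 35.2 to 39.0, and none of the 10 was a promoter region. Of these 10 regions, 2 matched the mitochondrial genome and 6 had another copy in the reference, with Nxph1 in both counts. The genes with the most regions within 50 kb included long and short ones: Gm20388 had 129 regions over an annotated length of 4435 kb, Fgfr2 had 38 over 2961 kb, Gse1 26 over 353 kb, Rere 20 over 340.3 kb, Nav2 19 over 701 kb and Sae1 19 over 67.6 kb. Inpp5b, with a length of 59.7 kb, and the histone genes Hist1h2ad, Hist1h2bf and Hist1h3d, with lengths of 0.572, 0.461 and 1.25 kb, had 18 regions each. The 100 kb window with the most regions was on chromosome 13 from 23500001 to 23600000, within a histone gene cluster, with 17 regions. It was followed by the windows of Fosb, Ercc1 and Ercc2 on chromosome 7 from 19300001 (14 regions), of Klf1, Prdx2 and Junb on chromosome 8 from 84900001 (13) and of Aurkb and Per1 on chromosome 11 from 69000001 (13). Windows with 12 regions held Lamtor3 and Dapp1 on chromosome 3, U2af2 and Rplp2 in separate windows on chromosome 7, Stk11 and Cirbp on chromosome 10, and the alpha-globin genes on chromosome 11.

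Chromosome X had few regions. It held 459 regions, or 2.68 per Mb, against 7.72 on the median autosome, a ratio of 0.348 in the conservative list and 0.394 ± 0.00265 over the replicates (SD, n = 2). Per protein-coding gene the ratio was 0.494. The ratio was 0.432 for promoter regions and 0.259 for distal regions. Among the autosomes, chromosome 11 had the most regions per Mb (11.7) and chromosome 14 the fewest (5.56). Chromosome Y had 2 regions, and the labels give the cells as male.

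Regions called in 1 replicate only were weak and mostly distal. Replicate 1 had 1661 of them and replicate 2 had 3203. Of these, 27.6% and 26.8% were promoter regions, against 63.0% of the shared regions in each replicate (odds ratios 0.225, 0.2004 to 0.252, and 0.215, 0.197 to 0.234; p = 4.29e-165 and 2.11e-300, Fisher's exact tests). They carried a GATA motif more often than shared regions (odds ratios 1.92 and 1.93, p = 4.40e-33 and 4.93e-56, Fisher's exact tests). These p-values cover counting error within each library and not the spread between replicates. Among regions below the median signal of each list the differences were smaller, with odds ratios of 0.416 and 0.385 for promoters and 1.24 and 1.25 for GATA. Within distal regions alone the GATA direction turned, with odds ratios of 0.863 (0.760 to 0.980) and 0.886 (0.802 to 0.979). Their median signal percentile was 18.3 and 22.0, against 55.5 and 59.2 for shared regions. Hbb-bt, with a region in replicate 2 and not in replicate 1, was among the genes concerned.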

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

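The search of the scaffolds and of the archived list, with its motif tests, was chosen after the data were seen. Peaks on unplaced or unlocalized scaffolds, which no comparison above uses, numbered 105 in the ranked list of replicate 1 and 120 in that of replicate 2, or 0.264% and 0.271% of the peaks. They lay on 15 and 19 scaffolds, 14 of them in both replicates, and 38 and 46 of the peaks stood on 1 scaffold. The archived replicated list held 101283 regions that overlap no region of the other lists, 64.2% of its 157788 regions, with a median signal of 3.14 against 5.89 for its other regions. Promoters made up 6.07% of these additional regions. Near their distal summits the GATA motif had an odds ratio of 1.205 (95% interval 1.19 to 1.22), the E-box GATA composite 2.20 (2.06 to 2.36) and CTCF 22.5, against 2.22, 8.62 and 98.1 for the regions of the archived list that are also in another list. How the archived list was made is not given in the sources used here, and no explanation of these values was tested.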

How the results depend on the processing

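The alternatives that use the archived list, leave out the 100 regions of largest signal, take 1 gene per locus or use the signal value for the correlation were chosen after the data were seen. Of 79 values under alternatives for the summary results, 46 counted as unchanged and 33 did not. Unchanged meant within the SD of the replicates for the promoter share and the chromosome X ratio. It meant within an interval of counting error for the shares of shared regions and the ratios of list sizes. For the correlation it meant within an interval across peaks, which are not independent, and for counts within 1.5 times the main count. For the odds ratios of regions called in 1 replicate only, it meant the same direction and side of the test. Those odds ratios still shifted below the median signal, in replicate 1 from 0.225 to 0.416 for promoters and from 1.92 to 1.24 for GATA. The shares of shared regions (88.1% and 79.4%) became 84.7% and 76.2% with reciprocal overlap, 83.9% and 75.5% with summits within 100 bp, 83.2% and 74.3% in the pseudoreplicated lists and 84.1% and 84.0% in lists of equal length. The rho of 0.786 was 0.810 over promoter peaks, 0.726 over distal peaks and 0.858 for the signal value, and the rescue ratio of 1.03 was 1.00 in the looser lists. The promoter share of 47.3% was 27.4% in the replicated list, 14.01% in the archived list, 62.7% above the median signal, 43.1% and 51.2% with promoters of 500 bp and 2 kb, 54.2% when every summit counted and 55.5% to 58.8% without either replicate. Above the median signal, 1 list in place of 5 had more promoter regions and 3 in place of 5 had more distal regions; with CpG-matched random lists, 2 in place of 6 had fewer promoter regions; within 20 kb, 3 lists in place of 5 had more distal regions, and with lists matched on gene length 6 did. The membrane list and the transcription factors turned to 28.6% and 25% above the median signal, below other genes and not past the test (adjusted p = 0.877 and 0.793, Fisher's exact test). Against shuffled sequence 14 motifs in place of 8 were enriched at promoters, and GATA turned to 1.299, NF-E2/AP-1 to 1.48, RUNX to 1.498, STAT to 2.79, MEF2 to 4.004 and the first scrambled pattern to 1.13; NF-E2/AP-1 was at 1.00 in the archived list. The chromosome X ratio of 0.348 was 0.352 in the pooled pseudoreplicate list and per base that is not N, 0.312 in the replicated list, 0.472 above the median signal, 0.344 without the 100 regions, 0.494 per gene and 0.392 to 0.395 without either replicate. Except where the setting itself takes fewer or weaker regions, the cause was not tested. Among single lists, 105 of 120 promoter values and 115 of 135 distal values stayed on their side of the test, as did 305 of 323 motif values. The direction turned in 2 promoter values and 7 motif values where the main or the alternative value was past the test. These did not count as unchanged. Among the values that did, those past the test kept their direction, while a value not past it could turn. The globin genes turned so without replicate 2, at 33.3% with a promoter region against 38.8% of all genes. A further 7 odds ratios, of HNF1 and the estrogen response element, had no finite value because background or summits held no match. Of named genes, 410 of 455 promoter calls stayed the same. Their distal counts were tallied together with the number of distal motifs enriched and the distal GATA odds ratio, 475 values in all. Of these, 272 stayed the same, which for a count means within 1.5 times the main count. No paired analysis was possible because there is 1 group. Read depth is unknown, so its effect on weak regions could not be measured.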

Other observations

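The tests on the 44 regions outside promoters and the comparison of X signal at matched −log10 p were chosen only after the result was seen. The bounds of all other tests here were set before the values they measure were seen.

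GATA motifs were spread unevenly over distal regions of different strength, a difference that was described and not tested. The share with a GATA motif near the summit was 53.8% of 1225 distal regions in the lowest 10% by signal and 30.4% of 359 in the highest 10%, while the E-box GATA composite went from 7.02% to 4.74%, with a maximum of 10.96% in between. Of 5 patterns measured, CTCF motifs lay closest to the summit, a median of 15.5 bp away, against 34.5 bp for GATA, 35.0 bp for the composite, 31.5 bp for KLF and 52.5 bp for the first scrambled pattern. Of the genes with a promoter region, the open progenitor genes stood at a mean signal percentile of 33.1 and the open housekeeping genes at 64.2.

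Around the genes of the 5 red cell lists, 36 of 244 distal regions carried the composite, against 872 of the 10339 other distal regions (odds ratio 1.88, 1.31 to 2.69, p = 0.00112, Fisher's exact test), and GATA alone was also more frequent (odds ratio 1.70, adjusted p = 0.000649), while the KLF motif (1.35, adjusted p = 0.132) and CTCF (0.764, adjusted p = 0.629) were not past the test. Over all 10583 distal regions, among 21 spacers from 0 to 20 bp between the CTG and the WGATAA, the odds ratio was largest at 8 bp (18.2), followed by 7 bp (9.91), with 5.48 as the largest and 3.78 as the median of the others. The spacer was not tested near red cell genes alone, and no file here measures binding of TAL1 or GATA1.

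The regions of largest signal were set against 3 explanations: mitochondrial sequence, repeated sequence and CTCF sites. Among the 100 strongest regions, 8 matched the mitochondrial genome and 5 carried a CTCF motif, both under the bound of 10 set in advance. Another copy in the reference was found for 25, against 3 of 100 random regions. The bound of 10 cannot speak for regions far from genes, because 56 of the 100 were promoter regions. Of the 44 others, 15.9% matched the mitochondrial genome (0.180% of other regions outside promoters), 45.5% had another copy (6.00% of random ones) and 6.82% carried CTCF (8.38%). Under the bounds set for these 44, the mitochondrial match and the copies were left undecided. The CTCF share argued against CTCF sites as their main source. For 23 of the 44 (52.3%) a copy or a mitochondrial match may account for part of the signal, while the other 21 stay without a tested explanation. Apart from CTCF sites, the single group of the design gives no biological explanation to test.

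The low number of regions on chromosome X was not fully accounted for by gene density. The ratio was 0.348 per Mb and 0.494 per gene, still under the bound set in advance. Promoters poor in CpG are a candidate explanation for part of it: 28.7% of X genes had a promoter region, against 43.3% of autosomal genes and 33.3% of CpG-matched ones, which leaves a difference of −4.56 points (permutation p = 0.0004). The CpG comparison covers promoter regions only, while the ratio per Mb was 0.432 for promoter regions and 0.259 for distal regions. It was predicted that a single X in male cells would lower the signal, although the scaling of that signal is not given. The promoter signal was higher on X by 0.27 on the log2 scale (0.17 to 0.35), and by 0.15 and 0.16 in the replicates' own lists. That met the bound set against a single X. That bound was wrong, because at matched −log10 p the signal of X promoters was higher by 0.21 (0.18 to 0.27), above every autosome (−0.17 to 0.11), so the signal is not on the same scale on X and does not measure copies. The 90th percentile of −log10 p differed on X by −0.16 on the log2 scale (−0.28 to −0.06). That lay on the side of its bound set against a single X, but its interval crosses the bound. Both readings cover only X promoter regions that were called, so they cannot show regions that were missed. The X ratio per Mb was 0.472 above the median signal and 0.221 below it. The labels give the cells as male, and whether a single X lowers the number of regions stays open.

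The promoter regions of red cell genes ranked low by signal, with a mean percentile of 42.2 over 67 open genes. Low CpG content at the most upstream start site does not account for this. Random open genes matched on that CpG ratio had a mean of 65.4, a difference of −23.2 points (permutation p = 0.0002, the smallest that the permutations can give). The ranked region could stand at another start site of the gene, and the CpG ratio there was not matched. The low rank was not particular to red cell genes. Open progenitor genes stood at 33.1 against 66.0 for matched genes (adjusted permutation p = 0.002). Housekeeping genes stood at 64.2 against 68.2 (adjusted permutation p = 0.475). Depth and the scaling of the signal were not tested as explanations, and the single group of the design gives no biological explanation to test.

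Of the regions called in 1 replicate only, 91.3% overlapped a peak of the other library's looser list, and their median GC content differed by 0 points between the replicates (52.7% in each).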
